A study of Mus musculus with 4 samples.

How the data were processed

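RNA was measured in 4 libraries of sorted splenic B220+ YFP+ cells from spleens of immunised C57BL/6 control mice, 1 group, by poly(A)-selected single-end sequencing with reads of 50 nt on DNBseq, with 20 M reads planned per library. Per the submitters' processing notes, FastQC, STAR 2.5.2b and featureCounts 1.6.0 were used with the mm10 build. The annotation release, the strand setting and the treatment of reads with several matches were not given in the sources used here. The deposited values are whole-number read counts per gene, not normalised, 1 table per library, with Ensembl gene identifiers, types and symbols. Totals ran from 13777954 to 14629025 counts, so that 3 counts, used here as the limit that a count of 0 allows, correspond to 0.205 to 0.218 CPM.

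Gene length (the union of exons) and position came from GENCODE M21 (GRCm38, the assembly named mm10). Of 37646 identifiers, 37536 matched it without the version suffix, 36825 with it, and 110 did not match and entered no TPM. TPM was computed from the deposited counts and these lengths. A gene whose symbol named more than 1 row, or that had no length, was left out of list levels. Every count column was used.

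32 gene lists, 6 differences between lists, 2 immunoglobulin shares, a test of variation, a split of the libraries and the rule for naming genes were fixed before the data were examined. List levels are medians of log2(TPM + 1). Differences between lists were taken within each library and tested with a two-sided exact sign-flip permutation over libraries and a two-sided permutation of list membership across genes (exact for the shorter pairs of lists, otherwise 100000 permutations), the latter adjusted by Benjamini-Hochberg. Genes of a list are not independent, which makes the across-gene p approximate. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only since reads without molecular identifiers are not independent molecules.

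Variation between libraries was tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, an intercept-only glmQLFit with legacy = FALSE). The quasi-dispersion of each gene over its trend was referred to the upper tail of the F distribution and adjusted by Benjamini-Hochberg at 0.05. The biological coefficient of variation was 21.8%. Lists and V segments were compared with all tested genes by two-sided Fisher's exact tests. Splits of the libraries were tested with glmQLFTest and with DESeq2 1.42.0, and limma 3.58.1 served as an alternative for variation. The spread of each list's mean was set against 10000 random lists matched on expression. Python 3.11.15 with scipy 1.17.1 did the rest.

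Tools were tested on simulated counts drawn from the libraries' means and sizes with 200 genes changed. For the variation test, 82.0% of genes changed 4-fold in 1 library pattern were recovered among 11755 tested, 98.0% at 16-fold and 70.5% at 64-fold, and 94.0%, 100.0% and 100.0% with the robust option. The simulated genes had only the trend's dispersion, whereas real genes also scatter around it, so recovery in the data can be lower. In the data Ighv5-17, picked after its value was seen, had a 55-fold range between libraries and did not pass (edgeR quasi-likelihood adjusted p = 0.0594). For the split of libraries, 99.5% were recovered at 4-fold among 11973 genes. In 40 simulated pairs of lists of 18 and 12 genes, the across-gene test gave p under 0.05 in 0% without a shift, 12.5% with a shift of 1 log2 unit and 70.0% with a shift of 3, so differences of 1 unit between such lists are often missed.

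Genes named in the text were chosen by that rule: a set of 23 genes, the 3 highest and the lowest measured member of each list, the 10 most abundant genes, and the genes with the smallest p among those passing the variation test (up to 15, and 3 among immunoglobulin and T cell receptor segments) and the split (5 in each direction). Others are said to have been picked after their values were seen, apart from the further members of fixed lists given as examples. Alternatives were another normalisation, filters on low counts, pseudocount 0.1, list means, values without gene length, other tools, segments left out, and each library left out in turn.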

Results

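Poly(A)-selected RNA was sequenced from splenic B cells of C57BL/6 mice that carried a Cre recombinase driven from the Ighg1 (Cg1) locus and a YFP reporter that Cre switches on. Mice had been immunised with sheep red blood cells on 2 occasions 20 days apart, and spleens were taken 10 days after the second injection. Living cells positive for B220, the B cell form of CD45, and for YFP were sorted. The labels name them normal germinal centre B cells, the antigen-activated cells that mutate and select their antibodies. The reporter also marks memory and plasma cells in which Cre was once active, so the sorted cells may be a mixture. B220 should limit plasma cells. All 4 libraries belonged to this 1 group, and the lymphoma samples named in the study's design text were not analysed here, so the comparisons below are between gene groups within a library and between the libraries. Libraries are numbered 1 to 4. The labels do not say that each library came from a separate animal, and the spread between these samples may be technical in part. P-values of the sign-flip, edgeR and DESeq2 tests measure only that spread. Those of permutations across genes, of random lists and of Fisher's exact tests take genes, not samples, as units. Library 3 alone carried Y-linked transcripts (Ddx3y at 1307 counts, at most 3 in the others) and nearly lacked Xist (6 counts, at least 8689 in the others). It thus did not share its source animals with the others, and sex cannot be separated from any other difference of library 3.

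The total count per library lay between 13777954 and 14629025. Of 37646 genes listed, 31026 had at least 1 count and 12475 reached a mean counts-per-million (CPM) value of 1. Pairs of libraries correlated across these 12475 genes with Pearson's r between 0.968 and 0.982 on the log2 CPM scale, genes not being independent replicates. Levels are given as transcripts-per-million (TPM) values, mean ± SD, n = 4, unless a library is named. The 10 most abundant genes were the mitochondrial mt-Co1, mt-Cytb, mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5, mt-Nd6 and mt-Rnr2, the kappa light chain constant gene Igkc (55073 ± 16367) and Cd74, the invariant chain of MHC class II (13180 ± 2781). Mitochondrial genes took 20.5% ± 2.17 of the counts and immunoglobulin genes 4.33% ± 1.43. The mt-Nd6 level is uncertain, since that gene lies opposite other mitochondrial transcripts and use of strand in counting was not stated.

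The transcripts that define germinal centre B cells were present in every library. The highest of 18 germinal centre genes were Neil1 (539 ± 162), a DNA glycosylase, Mef2b (512 ± 73.6), a transcription factor that acts upstream of Bcl6, and Basp1 (285 ± 77.8). Bcl6 itself, the transcriptional repressor that germinal centre cells require (chromosome 16, 23965052 to 23988852, mm10), stood at 71.9 ± 24.5. The death receptor gene Fas stood at 78.3 ± 14 and the confinement receptor gene S1pr2 at 47.1 ± 11.1. Of the 18 genes, 17 exceeded 1 TPM in all 4 libraries, and Sugct was at 0.182 ± 0.196.

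Transcripts of the B cell stages before and after the germinal centre were set beside this list. Different genes are compared within the same cells, and no separate naive, memory or plasma cells were measured. The differences therefore cannot say how much of each programme the sorted cells carried. The memory and naive lists share Cd38, Ccr6, Klf2 and Gpr183. The germinal centre list was 4.67-fold above the memory B list, by 2.23 ± 0.61 on the log2(TPM + 1) scale. It was higher in 4 of 4 libraries, with library 2 lowest at 1.31. The naive follicular list was at nearly the same level as the germinal centre list, at a difference of 0.30 ± 0.36 (-0.19 in library 2, 0.24 to 0.59 in the others, 0.46 ± 0.19 without library 2), and was led by Klf2 (1058 ± 407), a factor of quiescent lymphocytes, the low-affinity IgE receptor gene Fcer2a (417 ± 111) and Ighd (362 ± 84.9), the IgD constant gene of cells that have not switched. Cd38, low on germinal centre cells of mice, stood at 22.8 ± 7.61. The plasma cell list was also close to the germinal centre list, at a difference of 0.16 ± 0.55. It combined abundant secretory genes, Jchain at 1251 ± 422, Xbp1 at 201 ± 39.6 and Txndc5 at 189 ± 20.6, with low levels of Prdm1 (10.3 ± 2.52), the master regulator of plasma cells, the surface marker gene Sdc1 (13.5 ± 4.61) and Tnfrsf17 (5.08 ± 2.52).

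A permutation of list membership across genes gave p = 0.00126 for the difference from the memory list (adjusted p = 0.00378 over 6 planned differences), p = 0.535 for the naive list and p = 0.989 for the plasma list (adjusted p = 0.989 for both). The exact sign-flip test over libraries gave p = 0.13, 0.25 and 0.5, in the order memory, naive, plasma, where 0.13 is the smallest p that 4 libraries allow. With list means in place of medians the difference from the naive list changed direction, to -0.05, and without gene length it was 0.10. The difference from the plasma list was 0.63 by list means, 0.51 without gene length, and 0 to 0.34 with 1 library left out. The memory list contains Bcl2 (8.70 ± 0.70), the survival gene that germinal centre cells repress, Cd80 (3.67 ± 1.35) and Cd44 (48.3 ± 6.43).

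**Figure D1:**
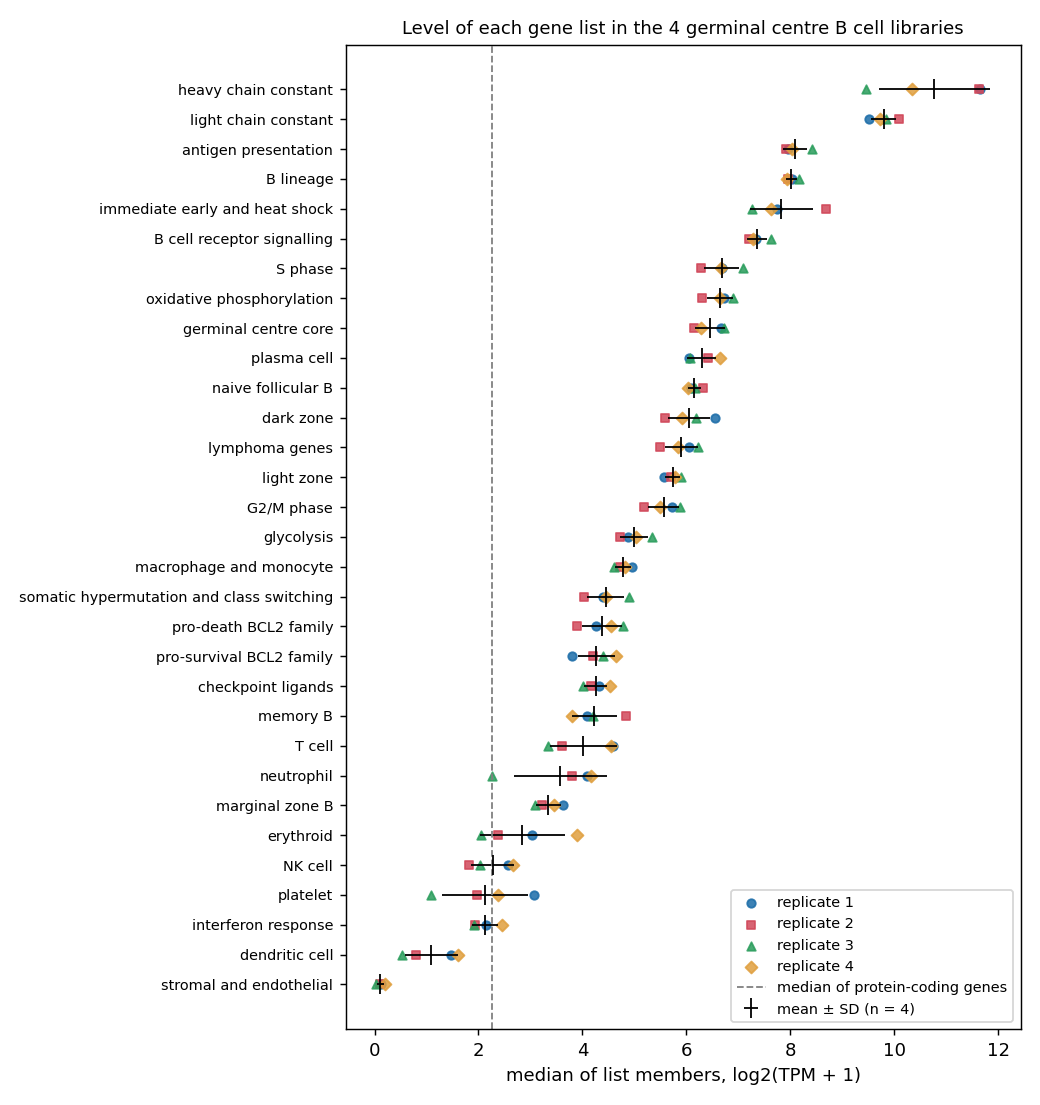
Median log2(TPM + 1) of the measured members of 31 gene lists (y axis, sorted by mean) in each library (symbols), with the mean and SD over 4 libraries (black) and the median of 17201 protein-coding genes with a count (dashed). Germinal centre (6.46), plasma (6.29) and naive (6.15) lists lie side by side, memory genes (4.23) and T cell genes (4.02) lie lower, and stromal genes (0.12) lie at the bottom.

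Dark and light zones are the germinal centre compartments in which cells divide and mutate and in which they are selected. Genes of both zones were expressed. The dark zone list was led by the chemokine receptor gene Cxcr4 (334 ± 61.2) and by Tcf3 (168 ± 29.8), with Foxo1, a factor that maintains the dark zone, at 64.2 ± 10.0. The light zone list was led by the NF-κB inhibitor gene Nfkbia (530 ± 64.9), Cd83 (267 ± 50) and Myc (243 ± 58.4), with Cd86 at 66.9 ± 19.8 and Irf4 at 144 ± 35.3. The dark zone list lay 0.32 ± 0.47 above the light zone list, in 3 of 4 libraries, a difference smaller than the spread between libraries. The exact permutation across genes gave p = 0.775 (adjusted p over the 6 differences 0.989) and the exact sign-flip test p = 0.25. Library 1 set most of the difference, at 0.98. Without library 1 it was 0.11 ± 0.20, by list means 0.52 ± 0.51 and without gene length 0.86 ± 0.35.

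Cells were in cycle. All 13 S phase genes and all 17 G2/M genes exceeded 1 TPM in every library, with the replication helicase genes Mcm5 (227 ± 56.5), Mcm3 (199 ± 63.9) and Mcm6 (170 ± 53.9) and the mitotic genes Mki67 (214 ± 73.5), Top2a (116 ± 36.4) and Cdc20 (106 ± 17.5) at the top of their lists. The G2/M list lay 1.11 ± 0.11 below the S phase list in 4 of 4 libraries by log2 medians, which was not past the threshold across genes (permutation p = 0.121; an added difference). Genes of hypermutation and class switching had a list median of 21.1 TPM, from Supt5 at 110 ± 24 and Rpa1 at 95.7 ± 21.4 to Apex2 at 4.42 ± 0.69. The translesion polymerase gene Polh stood at 22 ± 7.66.

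The balance of the BCL2 family was examined because germinal centre cells are prone to apoptosis. Mcl1 was the most abundant survival gene (284 ± 32.9), followed by Bcl2l1 (21.6 ± 2.27), Bcl2a1b (19.3 ± 5.22), Bcl2a1d (18.4 ± 4.84) and Bcl2. The pro-death list was led by Bak1 (94.3 ± 20.3), Bax (90.5 ± 17.2) and Bid (74.6 ± 13.2), and Hrk was near 0 (0.021 ± 0.027). The survival list minus the death list was -0.11 ± 0.37 by medians, positive in 2 of 4 libraries (exact permutation across genes p = 0.893; exact sign-flip p = 0.625). By list means it was 0.22, without library 1 it was 0.008, without gene length -1.01 ± 0.38 and for members with a mean of at least 1 CPM -0.74 ± 0.23, so neither sign nor size was fixed. Bcl2a1b and Bcl2a1d are near-identical copies, and their separate levels are uncertain.

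B lineage transcripts stood far above those of other cell types. The B cell receptor genes Cd79b (1399 ± 210) and Cd79a (1073 ± 95.2) were among the highest of the list, and Ptprc, which encodes the CD45 antigen used in the sort, stood at 123 ± 16. The B lineage list lay 16-fold above the T cell list, by 4.0 ± 0.71 log2 (higher in 4 of 4 libraries; permutation across genes p = 2e-05, adjusted p = 0.00012; exact sign-flip p = 0.13). It exceeded the macrophage and monocyte list 9.46-fold, the neutrophil list 21.7-fold, the erythroid list 36.3-fold, the NK cell list 53.8-fold, the platelet list 59.5-fold, the dendritic cell list 121-fold and the stromal list 240-fold, each in 4 of 4 libraries and each with an across-gene permutation p adjusted over 9 added differences of at most 0.00172.

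T cell transcripts were nevertheless measurable in every library. The T cell receptor constant gene Trac was at 135 ± 61.9, Trbc2 at 67.0 ± 28.5, Cd4 at 15.6 ± 8.05 and Cd8b1 at 33.0 ± 16.7, whereas the helper cytokine gene Il21 was at 0.098 ± 0.051. Lck, a kinase gene also expressed in some B cells, was the highest of the list (139 ± 23.7). The other lists were headed by the lysozyme gene Lyz2 (68.2 ± 34.1) and Hmox1 (70.8 ± 14.5) for macrophages, S100a9 (91.0 ± 46.3) for neutrophils, Hbb-bs (56.5 ± 43.5) for erythroid cells, Gzma (30.4 ± 10.7) for NK cells, Flt3 (17.3 ± 2.55) for dendritic cells, Ppbp (17.5 ± 16.3) for platelets and Pecam1 (33.4 ± 3.0) for stromal and endothelial cells. The erythroid genes Hba-a1 (36.0 ± 16.1) and Hba-a2 (32.0 ± 14) share nearly all their sequence, and the split between them is uncertain.

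Signalling and antigen presentation genes were among the most abundant groups. All 16 B cell receptor signalling genes exceeded 1 TPM in every library, down to Malt1 at 21.4 ± 1.32. MHC class II genes H2-Ab1 (2766 ± 540) and H2-Eb1 (2162 ± 341) followed Cd74 at the head of the antigen presentation list, and the costimulatory gene Cd80 was its lowest member. Of 30 genes recurrently altered in B cell lymphoma, fixed as a list because the study set these cells against lymphomas, 29 exceeded 1 TPM in all 4 libraries. B2m (3308 ± 501), Cd79b and Mef2b were the highest and the cell cycle inhibitor gene Cdkn2b (1.10 ± 0.40) the lowest. Oxidative phosphorylation genes, led by Atp5a1 (544 ± 117) and Atp5b (480 ± 99.3), lay above glycolysis genes, led by Ldha (238 ± 58.6) and Pkm (185 ± 37.4). Of 15 glycolysis genes 14 entered, down to Pgam1 (4.21 ± 1.64), and the oxidative phosphorylation genes ran down to Atp5g1 (2.5 ± 0.22). The treatment of reads with several matches was not given, so levels of genes with near-copies elsewhere are uncertain in both lists. The glycolysis minus oxidative phosphorylation difference was -1.65 ± 0.14 log2, the same direction in 4 of 4 libraries (permutation across genes p = 0.0307, adjusted p = 0.0345; a difference added after the data were examined).

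Heavy chain constant genes were compared because Cre was driven from Ighg1. Ighm, the constant gene of IgM, gave the largest mean share of heavy chain constant counts, 38.2% ± 12, and Ighg1 (chromosome 12, 113325240 to 113330523) gave 26.5% ± 10.7. Ighg3 gave 11% ± 8.07, Ighg2b 11% ± 3.28, Ighg2c 7.96% ± 1.81, Igha 3.49% ± 1.81, Ighd 1.47% ± 0.70 and Ighe 0.368% ± 0.348. Classes other than Ighm and Ighd together made up 60.3% ± 12.6. Divided by gene length, the order turned to Ighg2c 12.7%, Ighg3 9.31% and Ighg2b 8.71%. Shares of RNA are not shares of cells, and Ighg2b and Ighg2c are similar enough that reads could be shared between them.

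The class profile differed from library to library by far more than counting error. Ighg1 held 42.5% of 325953 heavy chain constant counts in library 4 (exact 95% interval 42.3 to 42.6%) and 21.3%, 21.8% and 20.5% in libraries 1, 2 and 3. Without library 4 the mean Ighg1 share was 21.2%. In library 3 Ighm held 55.5% (55.2 to 55.7%) and the switched classes 42.1%, against 62.3 to 70.7% in the other libraries. Library 3 also had the lowest plasma cell list by mean log2 CPM (5.81, 6.46 to 6.74 in the others), though not by median log2(TPM + 1) (6.07, against 6.04 in library 1), the lowest Jchain (632 TPM, 1368 to 1574 in the others) and the smallest share of immunoglobulin counts (2.35%, 4.25 to 5.48% in the others). Ighg3 held 17.3% and 18.6% in libraries 1 and 2 and 5.02% and 3.16% in libraries 3 and 4, and Ighe 0.065% and 0.081% against 0.571% and 0.753%. Intervals cover counting error only, and no test between groups applies to these shares. Kappa chains dominated the light chains: Igkc (chromosome 6, 70726435 to 70726966) took 95.8% ± 1.47 of light chain constant counts, and Iglc1, Iglc2 and Iglc3 took 2.14% ± 0.79, 1.13% ± 0.29 and 0.978% ± 0.498, with Iglc2 and Iglc3 near-identical.

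**Figure D2:**
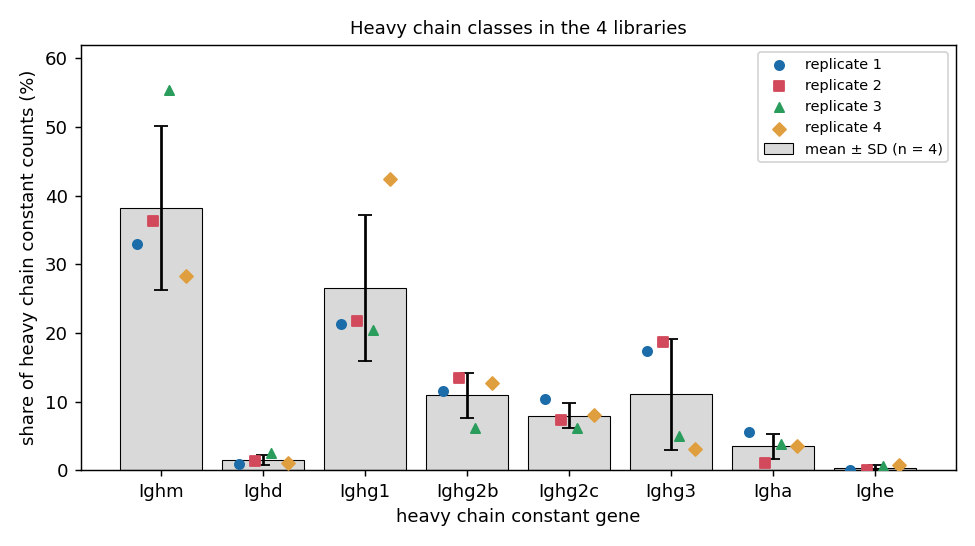
Share of heavy chain constant counts (%, y axis) held by each constant gene (x axis) in each library (symbols), with the mean (bar) and SD over 4 libraries (line). Ighm is highest in library 3 (55.5%), Ighg1 in library 4 (42.5%), and Ighg3 lies at 17.3 and 18.6% in libraries 1 and 2 against 5.02 and 3.16% in libraries 3 and 4.

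Heavy and kappa chains were led by a different immunoglobulin V segment in each library, V segments being the exons that encode the antigen-binding part of the receptor. Among heavy chain segments, Ighv6-6 led library 1 (9.71% of heavy V counts), Ighv5-17 library 2 (12.8%), Ighv1-7 library 3 (4.13%) and Ighv1-39 library 4 (16.1%). Among kappa segments, Igkv5-39 led library 1 (9.75%), Igkv14-126 library 2 (19.0%), Igkv8-30 library 3 (7.17%) and Igkv6-20 library 4 (7.98%). Igkv8-30 was not particular to library 3, as it held 7.64% in library 1. The effective number of segments, the inverse of the sum of squared shares, was 29.8, 30.1, 48.7 and 23.0 for heavy chains in libraries 1 to 4, and 29.0, 16.1, 36.1 and 32.2 for kappa chains. Lambda chains, with 3 segments listed, were led by Iglv1 in all 4 libraries (73.6, 83.1, 76.7 and 74.0%). V segment use was examined after the data were seen.

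Variation between libraries was tested gene by gene, to find which transcripts differed more than their expression level would give. Igkv14-126 (chromosome 6, 67896172 to 67896642) was the 1 gene of 11982 tested that passed: its normalised level was 1011 CPM in library 2 and 4.56, 1.35 and 12 CPM in libraries 1, 3 and 4 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0172). Without library 2 no gene passed. At an unadjusted p under 0.05 there were 595 of the 11982 genes, about the share that this threshold passes by chance. The 595 genes included 146 of the 167 tested V segments (87.4%) against 3.80% of other genes (Fisher's exact test p = 3.99e-173, adjusted p = 1.28e-171 over 32 sets). Of the 100 most variable tested genes, 83 were V segments. In the counts of variable genes, V segments include V pseudogenes. The filter on low counts kept only genes that reached its level in every library. Genes on in some libraries and off in others, the sex-linked genes among them, were therefore not tested. Without that filter 262 genes passed. With genes kept at a mean of 1 CPM, Ddx3y stood at 249, Xist at 213 and Eif2s3y at 155 times the trend, as seen in a test added afterwards.

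The robust form of the edgeR test called 63 genes, of which 58 were V segments and 2 the constant genes Ighe and Ighg3. The other 3 were the heat shock genes Hspa1a and Hspa1b, neighbours on chromosome 17, and Jun, an AP-1 transcription factor gene. DESeq2 marked 159 genes as dispersion outliers, 112 of them V segments, and limma-voom called 0. The 3 non-immunoglobulin genes did not pass the main test (adjusted p = 0.236 for Hspa1b, 0.238 for Hspa1a and 0.256 for Jun) and were picked after their values were seen. Jun ranged from 250.1 to 1821 CPM and Hspa1a from 5.75 to 57.3 CPM between libraries. Hspa1a and Hspa1b are near-identical, so reads of one can be counted to the other.

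**Figure D3:**
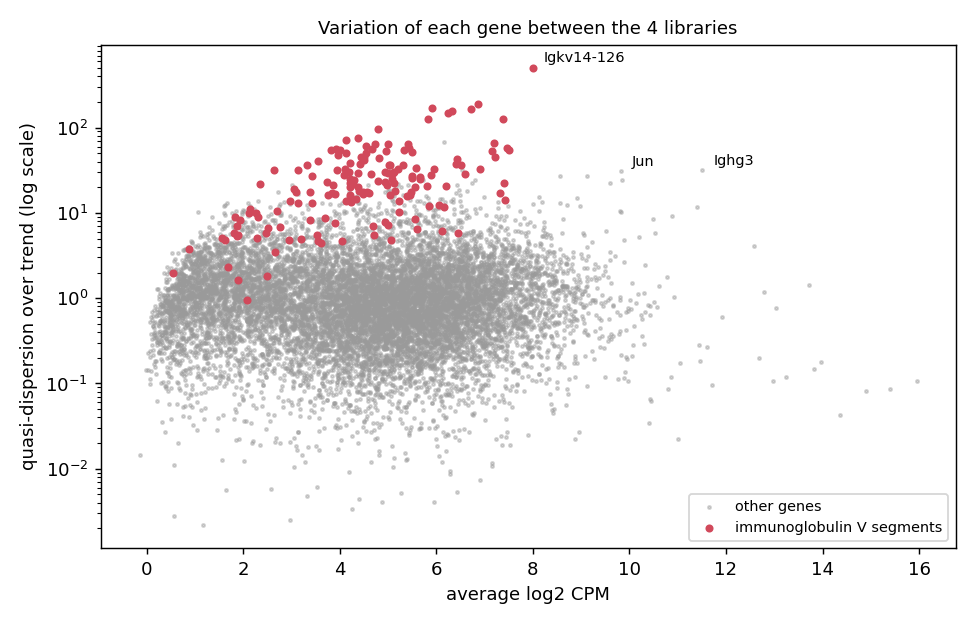
Quasi-dispersion of each of 11982 tested genes divided by the trend at its level (y axis, log scale) against average log2 CPM (x axis). Immunoglobulin V segments other than pseudogenes are in red and all other genes in grey. V segments form the upper edge, and Igkv14-126 is highest at 506 times the trend.

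Among the gene lists, platelet, T cell, immediate early and heat shock, and neutrophil genes differed most often between libraries at the unadjusted threshold. Only 2 platelet and 4 neutrophil genes were tested. Of genes outside each list, 4.88 to 4.97% passed that threshold. Of the 13 tested immediate early and heat shock genes, 10 had an unadjusted p under 0.05 (Fisher's exact test adjusted p = 2.26e-10), among them Fos (836 ± 488), Jun (604 ± 386) and Egr1 (268 ± 167), and Junb (1119 ± 276) headed the list. Of 13 tested T cell genes, 11 did so (adjusted p = 4.72e-12), Lck not among them. The same held for 7 of 14 plasma cell genes (adjusted p = 1.46e-05), 6 of 13 memory genes (9.92e-05), 5 of 12 naive genes (0.000748), 4 of 7 erythroid genes (0.000748), 5 of 8 heavy chain constant genes (9.41e-05) and 5 of 17 germinal centre genes (0.00358), among them Gcsam, Mybl1, Efnb1 and Bcl6. It also held for 2 of 2 platelet genes (0.00716), 3 of 4 neutrophil genes (0.00167) and 4 of 17 light zone genes (0.0228). None of the B lineage (18), B cell receptor signalling (16), antigen presentation (14) or G2/M (17) genes had an unadjusted p under 0.05. Adjusted over all genes, no member of these lists passed the main test, and 5 passed its robust form: Hspa1a, Hspa1b, Jun, Ighe and Ighg3. The counts at unadjusted p were added after the data were seen.

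List means were then compared between libraries, by a test added after the data were seen. Of 32 lists, 26 spread more than random lists of like expression (random-list test adjusted p under 0.05), B lineage (adjusted p = 0.0467) and G2/M (0.000246) among them. Members of a random list were drawn independently, so a list whose genes vary together can pass for that reason alone. The size of the spread is therefore given. It was widest for the sex-linked list, at 4.95-fold. The mean log2 CPM of immediate early and heat shock genes was 8.70 in library 2, 8.08 and 8.13 in libraries 1 and 4 and 7.15 in library 3, a 2.92-fold range (SD 0.64, permutation p = 0.0001 against 10000 random lists of like expression, the smallest p they can give, adjusted p = 0.000246 over 32 lists). The share of mitochondrial counts ran in nearly the same order, at 23.3% in library 2, 20.6% and 19.8% in libraries 1 and 4 and 18.1% in library 3. Not every member of the immediate early and heat shock list followed its mean. The heat shock genes Hspa1a (57.3, 32.5, 5.75 and 35.1 CPM in libraries 1 to 4) and Hspa1b (79.8, 43.3, 10.55 and 56.8) were highest in library 1. The T cell list was at 4.56, 3.78, 3.44 and 4.40 in libraries 1 to 4, a 2.17-fold range with the same p as the immediate early list. Platelet genes had a 3.58-fold range, erythroid genes 3.06-fold, neutrophil genes 2.12-fold, dendritic cell genes 1.94-fold and plasma cell genes 1.90-fold, and by this mean all 8 lists of other cell types were lowest in library 3. By median log2(TPM + 1) the NK cell list was lowest in library 2 instead (1.82, 2.02 in library 3), and by summed TPM so were the T cell, NK cell, macrophage and dendritic cell lists. The germinal centre list was lowest in library 2 (6.55) and highest in library 1 (7.15), while the naive list (7.54) and the memory list (5.91) were highest in library 2. The mean of the lymphoma genes was steadiest, with an SD of 0.023 against a median of 0.051 for random lists (permutation p = 0.93), though 2 of its 28 tested members, Bcl6 and Myc, had an unadjusted p of variation under 0.05. By median log2(TPM + 1) that list was not the steadiest, with an SD of 0.32 against 0.11 for the B lineage list.

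**Figure D4:**
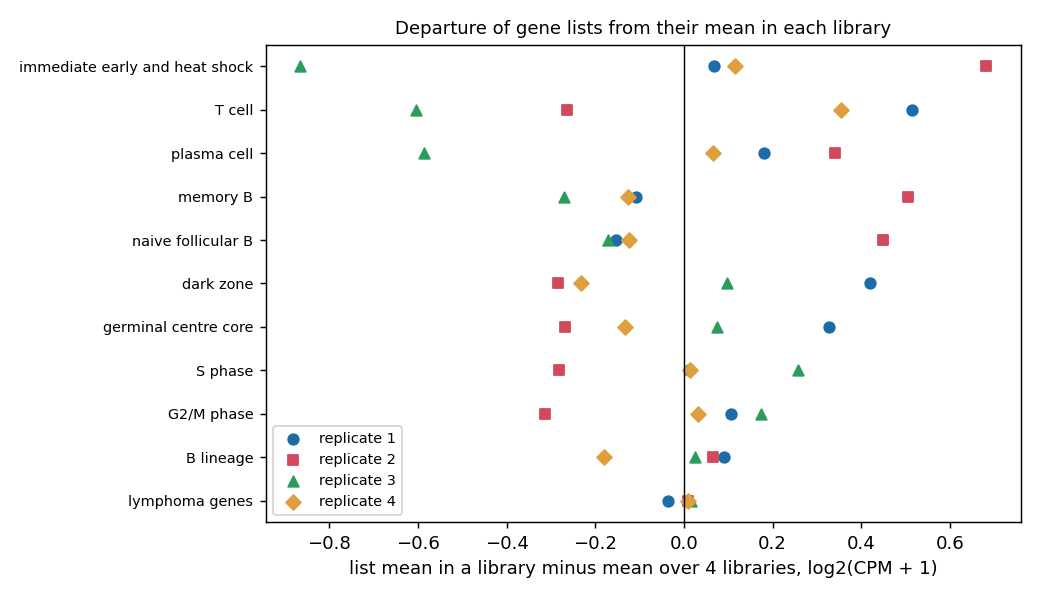
Mean log2(CPM + 1) of the members of 11 gene lists (y axis) in each library (symbols) minus the mean over the 4 libraries (x axis). Immediate early and heat shock genes span 1.55 log2 units from library 3 to library 2, T cell genes 1.12 from library 3 to library 1, and lymphoma genes 0.05.

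The numbers in the sample titles place libraries 1 and 2 close together and libraries 3 and 4 close together, and this split was run as a technical check, not as a comparison of the study. Of 13520 genes tested, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05, with 1397 at an unadjusted p under 0.05 (10.3%), against 331 and 465 for the other pairings of the 4 libraries, of which the first called 1 gene. DESeq2 called 110 genes for the title split and 19 and 22 for the other pairings. The smallest p belonged to Ighg3, 2.94 ± 0.27 (SE) log2 higher in libraries 1 and 2, with an edgeR adjusted p of 0.0702 and a DESeq2 adjusted p of 1.06e-57. Ighg3 was named after its value was seen.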

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

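In this part the within-total test of V segments and the light zone and T cell tests of the immediate early genes were chosen only after the result was seen, while the tests of V segment sequence, of further handling genes and of further naive genes were written down before their results were seen.

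A library was singled out when its gap to the nearest other library exceeded Dixon's 95% critical share of the range. Of 212 values examined, 15 stood apart, where chance gives about 1 in 20, or 10.6. They fell 2, 5, 6 and 2 times in libraries 1 to 4, so no library stood apart throughout. Library 3 had Fas at 99.14 TPM (69.9 to 73.6 in the others) and Ly6g, a neutrophil gene, at 0.7198 (0.487 to 0.503), which rests on 4 counts against 3 in each other library and is not told from them. Its Y-linked genes Ddx3y (42.62, others at most 0.0896), Eif2s3y (29.01, others 0) and Uty (2.58, others at most 0.0469) were expressed, with a sex-linked list median of 2.747 on the log2(TPM + 1) scale (others at most 0.014). Library 1 had Irf4 at 90.78 (156.5 to 163.7) and the platelet gene Ppbp at 41.87 (7.51 to 11). Library 2 had Cdc20 at 79.58 (110.9 to 116.2), Bcl2l2 at 1.577 (1.98 to 2.05), Pecam1 at 37.86 (31.4 to 32.4) and Igkv14-126 at 5553 (9.47 to 80.2), and its germinal centre minus memory difference was 1.307 log2 (2.48 to 2.59). Library 4 had the beta globin gene Hbb-bs at 121.7 (31.7 to 36.4) and an Ighg1 share of 42.46% (20.5 to 21.8%).

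Immunoglobulin V segments were the most variable group between libraries among the 11982 genes tested. The filter had removed genes low in any library, the sex-linked genes among them. Taken as a share of the V segment total, which removes differences in total immunoglobulin RNA, 201 segments, V pseudogenes among them, kept a median SD of 1.138 log2. Genes of like level had 0.261. Of these segments 97.5% had an SD above the median of their matched genes. Both values argue against total immunoglobulin RNA as the whole cause. Reads shared between near-identical segments are argued against by the 51 segments with at least 90% of their 50-nt words found in no other gene, whose median SD was 1.265 (quartiles 0.77 to 1.90). The design has 1 group, so no biological explanation was tested, and expansion of different B cell clones in each library stays open as a hypothesis.

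Immediate early and heat shock genes spanned 1.547 log2 from library 3 to library 2, where the mitochondrial share of counts was 18.1% and 23.3%, the lowest and the highest of the 4. Library 3 was also the 1 library with Y-linked transcripts, and the design cannot separate sex from this contrast. For a larger share of light zone cells, the light zone list was 0.188 higher in library 2 than in library 3, below the 0.774 required by the bound set afterwards. The dark zone list, however, was lower in library 2 (6.93) than in library 3 (7.31). A shift between zones need not move both kinds of list equally far, so this test cannot tell such a share apart. RNA of T cells as the whole cause is argued against by the T cell list, which was at 3.44 in library 3 and 3.78 in library 2 but differed by -0.618 from library 4 to library 2, while the immediate early list was 0.566 higher in library 2 than in library 4. The heat shock genes Hspa1a (32.5 and 35.1 CPM in libraries 2 and 4) and Hspa1b (43.3 and 56.8) went the way of the T cell list, so the argument does not cover them. A response of the cells to handling cannot be told apart: 14 further genes of such a response differed by 0.477 between libraries 2 and 3 (SD over genes 0.485, 11 of 14 higher), between the bounds written beforehand of 0.5 for it and 0.2 against it. No biological explanation named by the design was tested, as it has 1 group.

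In library 2 the naive list lay 0.45 log2 above its mean over libraries and the germinal centre list differed from its own mean by -0.269, so that they were 0.718 apart. A larger share of naive B cells cannot be told apart: 12 further naive genes differed by 0.22 between library 2 and the mean of the others (SD over genes 0.318, 10 of 12 higher), between the bounds of 0.25 for it and 0.1 against it. No biological explanation named by the design was tested.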

How the results depend on the processing

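The legacy quasi-likelihood fit, and the alternatives for levels of single genes and lists, were tests chosen only after the result was seen. Of 88 alternatives for 10 comparisons, 69 kept the main result, 3 turned the direction and 16 moved a count by over 1.5 times. For list differences, keeping it meant the same direction and side of the threshold. That held for 7 of 9 alternatives of survival minus death and 44 of 45 of the other differences. For the 12 alternatives of shares it meant a move of less than 1 SD, which leaving out 1 library gives by construction. For counts of genes it meant a move of at most 1.5 times. The germinal centre minus memory difference stayed between 1.79 and 2.53 log2, B lineage minus T cell between 3.72 and 5.08, the Ighg1 share between 21.2 and 28.5% and the Igkc share between 95.2 and 96.4%. Levels of 172 named genes and lists moved by less than 1 SD in all 860 alternatives, as leaving out 1 of 4 libraries does by construction, so only the TMM-scaled levels test this. With list means, germinal centre minus naive was -0.05 and survival minus death 0.219, and leaving out 1 library gave -0.248 to 0.008 for the latter. Without gene length, survival minus death was -1.01, dark minus light zone 0.86, germinal centre minus plasma 0.51 and germinal centre minus naive 0.10. With members of at least 1 CPM, survival minus death was -0.74. Germinal centre minus naive was 0.21 to 0.46 with 1 library left out. Germinal centre minus plasma was 0.63 by list means and 0 to 0.34 with 1 library left out. None of these passed the test across genes. The cause was not tested. For variation, the 1 gene became 10 without scaling beyond library totals, 262 without a filter on low counts, 159 with DESeq2 dispersion outliers, 0 with limma-voom, 63 with robust = TRUE, 0 with immunoglobulin and T cell receptor segments left out, 12 with libraries 1 and 2 against 3 and 4 as a term, 6 with the legacy quasi-likelihood, and 0 to 19 without a library (without replicate 2, 0; without replicate 3, 19). For the split of libraries the 0 genes became 110 with the DESeq2 Wald test and 13 to 79 without a library (without replicate 3, 13; without replicate 2, 79), where the lone library is assumed to vary like the others. The cause was not tested. No paired analysis was possible because there is 1 group. Counts of 3 or fewer, 0.205 to 0.218 CPM, are not told from 0.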

Other observations

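The test of sex-linked genes under another filter was chosen only after the result was seen.

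Interferon-stimulated genes stood near the level of the typical gene, with a list median of 3.66 TPM against 3.89 for 17201 protein-coding genes with a count. Irf7 (38.5 ± 7.31), a transcription factor that interferon induces, and Isg15 (13.9 ± 5.52) were among the highest of the list, and Ifi44 was at 0.137 ± 0.077. Ligands of immune checkpoint receptors were expressed: Cd86, Icosl (62.6 ± 8.20), the T cell costimulator, and Lgals9 (38.8 ± 3.30) led, Cd274, which encodes PD-L1, stood at 37.7 ± 13.8, and Nectin2 was at 0.818 ± 0.559. Of 11 such genes 10 exceeded 1 TPM in all 4 libraries. Marginal zone genes had a list median of 9.33 TPM, led by the Notch-regulated gene Dtx1 (107 ± 14.7), the complement receptor gene Cr2 (63.3 ± 10.6) and S1pr3 (16.9 ± 1.17), down to Tbc1d9 (2.35 ± 0.94).

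Markers of rarer cell types stood near the median gene or below it. NK cell genes had a list median of 3.83 TPM, with Klrd1 at 7.23 ± 2.83 and Klrb1c at 1.71 ± 0.84, platelet genes 3.75, dendritic cell genes 1.16, with Itgax at 6.01 ± 2.13 and Zbtb46 at 0.594 ± 0.324, and stromal and endothelial genes 0.078, with Col3a1 at 0.016 ± 0.023. Macrophage genes stood higher, at a median of 26.8, with Cd68 at 52.5 ± 9.97 and Spic, a factor of red pulp macrophages, at 2.54 ± 0.90. Neutrophil and erythroid medians were 12.4 and 7.11.

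Xist, the RNA that silences an X chromosome in female cells, had 8922, 8689 and 12160 counts in libraries 1, 2 and 4 and 6 in library 3, while the Y-linked Ddx3y had 1307 counts in library 3 and 3, 0 and 0 in libraries 1, 2 and 4. With genes kept at a mean of 1 CPM, the adjusted p of variation was 0.0514 for Ddx3y, Xist and Eif2s3y (edgeR quasi-likelihood). In mean log2 CPM, all 8 lists of other cell types were lowest in library 3, which did not hold for every list by median or summed TPM. On that mean, library 1 minus library 3 was 1.84 log2 for platelet, 1.12 for T cell, 0.89 for NK cell, 0.72 for dendritic cell, 0.61 for erythroid, 0.60 for neutrophil, 0.60 for macrophage and 0.27 for stromal and endothelial genes.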
